A study of Mus musculus with 32 samples.

How the data were processed

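RNA from mouse bone marrow-derived macrophages was profiled in 32 libraries, 4 in each of 8 groups. The groups crossed 3 factors: genotype (wild-type, or Trem2 knockout, T2KO in the labels), medium (low or normal M-CSF) and LPS (with or without). The labels give C57BL/6 as the strain of both genotypes. Per the labels' protocols, the cells were kept overnight in complete RPMI with 0.5% or 10% LCCM, and some were given LPS at 10 ng/ml for 4 hours. Taking low M-CSF as 0.5% LCCM and normal M-CSF as 10% is an inference, since no label joins the names to the percentages. The same protocols describe mRNA captured on oligo-dT beads and cDNA primed with barcoded oligo-dT. They then describe pooling by Actb qPCR values, ligation of a second linker and 12 cycles of PCR to strand-specific libraries, and they mention no molecular identifiers. Such libraries read the 3' ends of transcripts, so reads of a targeted gene measure only the part of the transcript that was kept.

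The deposited table holds raw counts per gene, which the authors did not normalise, for 24885 identifiers. The submitters' processing notes list STAR, HTSeq, DESeq2 and build mm10 without versions, and they state neither the annotation nor the strand setting of the counting. Gene symbols and mm10 positions came from the reference annotation by Entrez identifier, which matched 23969 identifiers (96.3%) with 99.5% of the counts. The other 916 identifiers stayed in the fit and were not named, and 8418 identifiers had no count in any library. Every library column was assigned to a group by its title. Total counts per library ranged from 3068863 to 15585423 (median 5596111), and no library fell below the depth limit fixed in advance, set relative to the median. A count of 3, the largest true count that an observed 0 allows at 95% confidence, corresponded to 0.193 CPM (counts scaled to library size) in the deepest library and to 0.978 CPM in the shallowest. Floors and intervals cover counting error only, because PCR copies without molecular identifiers are not independent molecules. The labels do not say whether the 4 libraries of a group came from separate mice or cultures, so every p measures the spread between these libraries.

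Counts were fitted in 1 model with a mean for each of the 8 groups with edgeR 4.0.16 (R 4.3.3). Normalisation used TMM, low counts were filtered with filterByExpr at its defaults, which left 11244 genes, and dispersions came from estimateDisp. Contrasts were tested with the two-sided quasi-likelihood F test (glmQLFit, glmQLFTest), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. The 14 comparisons were genotype in each of the 4 conditions, low against normal medium without LPS in each genotype, LPS in each genotype and medium, and 4 interactions. The interactions asked whether the genotype difference varied with the medium or with LPS, and whether the LPS response of wild-type cells varied with the medium. CPM values are TMM-scaled unless raw CPM is stated. Log2 fold changes are given with their standard errors (SE) and group means with their standard deviations (SD). The level of Trem2 was also compared by a two-sided exact permutation test on log2(CPM + 1) over the 70 arrangements of 4 against 4 libraries. The method was tested on simulated data in which known genes were changed. For the genotype comparison in low medium without LPS, edgeR recovered 16.4% of genes changed 1.5-fold, 58.2% of genes changed 2-fold and 95.5% of genes changed 4-fold, and 9 of its 122 calls were false. In normal medium it recovered 10.4%, 49.3% and 92.4%, with 6 of 107 calls false. For the medium in wild-type cells it recovered 5.97%, 64.2% and 90.9%, with 5 of 112 calls false. For LPS in wild-type cells in normal medium it recovered 8.96%, 67.2% and 80.3%, with 11 of 115 calls false. The simulation changed few genes and drew every library independently, so its rates need not hold for the real comparisons.

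Gene lists were written before the data were examined. They covered glycolysis, the TCA cycle, oxidative phosphorylation, pentose phosphate and nucleotide synthesis, cholesterol synthesis, fatty acid synthesis, LXR targets, autophagy, lysosome, ATF4 targets, ribosome biogenesis and ribosomal proteins. Others covered the cell cycle, hypoxia, the LPS inflammatory response, the type I interferon response, MHC class II, macrophage identity, damage- and lipid-associated macrophage genes (a list that holds Trem2 itself), alternative activation, apoptosis and the Trem family. Lists of other cell types held markers of neutrophils, monocytes, dendritic cells, osteoclasts and stromal cells. Of the 32 lists, 27 had at least 3 members among the genes tested. These were compared with all other genes by camera (limma 3.58.1, on voom values with a preset inter-gene correlation of 0.01), with adjustment over the 27 lists within each comparison. The lists of lymphocyte, erythroid, mast cell, sex-linked and mitochondrially encoded genes were too small to test. Some genes stand in more than 1 list. Camera compares a list with the other genes, so a shift common to all genes does not enter its p.

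Named genes were chosen by a rule fixed before the data were examined. For 4 main comparisons (genotype in each medium without LPS, low medium in wild-type cells, LPS in wild-type cells in normal medium) it took Trem2 and the 10 largest changes each way. Those genes had to pass the test, average at least 20 CPM and show no overlap between groups. It also took up to 3 members with the smallest p from each list that passed. Other comparisons contributed 3 genes each way, interactions 5 each way by p, and the Trem family could always be named. Predicted genes without an established name were left out. The text names part of this selection, and genes from outside it are marked as chosen after their values were seen. Alternatives fixed in advance were RLE size factors in place of TMM, no low-count filter, DESeq2 1.42.0, limma voom with quality weights, a fit of the compared groups alone, a block for the replicate number and omission of each library in turn. Lists were also tested with an estimated correlation, with the block and by ranks, and Trem2 with pseudocounts of 0.5 and 5. Chosen after seeing the data were thinning of every library to the smallest total, and summing of libraries 1 with 3 and 2 with 4 of each group. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).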

Results

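The series title names TREM2, a lipid-sensing receptor of microglia and macrophages, as a regulator of energetic and biosynthetic metabolism. The libraries measured polyadenylated RNA of macrophages that had or lacked Trem2, in low or normal M-CSF, the growth factor that keeps macrophages alive and dividing, with or without LPS, the bacterial product that starts the inflammatory response. Each of the 8 groups held 4 libraries (n = 4 in every group mean below). Without LPS, total counts per library were 5554661 to 12995945 in wild-type cells in normal medium and 4929113 to 6802071 in low medium. Knockout cells without LPS had 4748813 to 9148889 in normal medium and 5333519 to 15585423 in low medium. With LPS, wild-type libraries held 4137581 to 11415752 in normal and 3111552 to 4547552 in low medium. Knockout libraries with LPS held 4451472 to 8929399 in normal and 3068863 to 6248835 in low medium. Between 10799 and 13314 genes had counts in a library. Within 6 of the 8 groups, libraries 1 and 3 and libraries 2 and 4 resembled each other more than other pairs did. The chi-square per degree of freedom between the counts of 2 libraries was 4.17 to 10.3 in 14 of these 16 pairs and 10.3 to 86.0 between other libraries of a group. The exceptions were wild-type cells without LPS, where libraries 1 and 3 in normal medium reached 39.2 and libraries 2 and 4 in low medium 18.8. The labels do not say whether such libraries are duplicates of 1 sample. If they are, n is 2 per group in place of 4, and the SE and p values below, the exact p of Trem2 included, are smaller than such samples would give.

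Trem2 transcripts were lower in knockout cells in all 4 conditions, and the share that remained ranged from 1.81% to 25%. Trem2 (Entrez 83433) lies on chromosome 17 at 48346401 to 48352276 in mm10. In normal medium without LPS it stood at 36.3 ± 4.96 CPM in knockout and 305 ± 46.7 CPM in wild-type cells, or 11.9% of the wild-type level. In low medium without LPS the knockout kept 25%, at 115 ± 13.9 against 460 ± 70.1 CPM. With LPS the knockout kept 2.60% in normal medium (5.88 ± 2.28 against 226 ± 26.2 CPM) and 1.81% in low medium (6.01 ± 2.31 against 332 ± 47.4 CPM). All 4 knockout libraries lay below all 4 wild-type libraries in each condition (two-sided exact permutation p = 0.0286 each, the smallest that 70 arrangements can give). Reads at the 3' end report transcript that is still made and polyadenylated, whether or not it can encode the receptor. The neighbouring gene Treml1, which encodes a related receptor (Entrez 71326, chromosome 17 at 48359916 to 48367176), was higher in knockout cells without LPS. It reached 12.0 ± 1.14 against 1.67 ± 1.08 CPM in low medium (edgeR adjusted p = 5.7e-05) and 4.43 ± 0.77 against 0.976 ± 0.572 CPM in normal medium (edgeR adjusted p = 0.011). Without wild-type library 1 or 2 the normal-medium difference of Treml1 missed the threshold (edgeR adjusted p = 0.054 and 0.068). Treml2 was higher in knockout cells in low medium with LPS (20.2 against 8.26 CPM, edgeR adjusted p = 0.0049). Trem1, Trem3 and Treml4 did not pass in any of the 4 genotype comparisons, with the smallest adjusted p for Trem1 at 0.33 in low medium with LPS. The Trem family list as a whole, with 1 member higher, 1 lower and 4 not passing, gave camera adjusted p = 0.96 in low and 0.766 in normal medium without LPS.

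**Figure D1:**
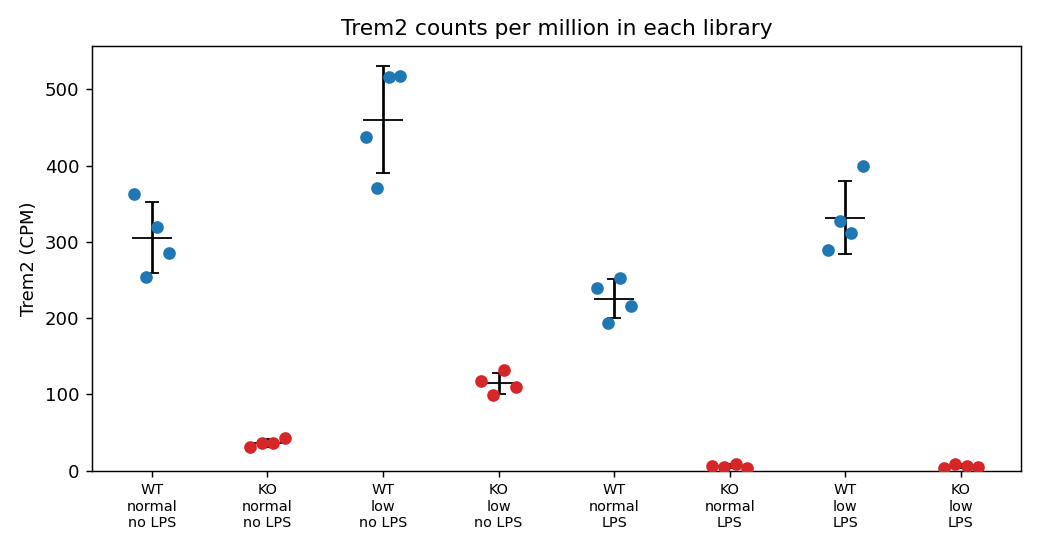
Trem2 level in CPM, counts scaled to library size (vertical axis, linear, from 0), in each of the 32 libraries, by genotype, medium and LPS; points are libraries, blue wild-type and red knockout, and bars give the mean and SD of 4 libraries. Knockout means were 115 CPM and 36.3 CPM without LPS in low and normal medium and 6.01 CPM and 5.88 CPM with LPS.

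In low M-CSF, wild-type cells had lower lists for the cell cycle, glycolysis, nucleotide and lipid synthesis, ATF4 targets and ribosome biogenesis, and higher lists for autophagy and LXR targets. This comparison of wild-type cells without LPS asked what the medium alone does. By the naming rule, the largest rise was in Thbs1, a secreted matrix glycoprotein (Entrez 21825, chromosome 2 at 118111876 to 118127133), from 1.84 ± 0.742 to 150 ± 27.8 CPM, a log2 change of 6.33 ± 0.26. Likewise the largest fall was in Ccl2, the monocyte-attracting chemokine (Entrez 20296, chromosome 11 at 82035577 to 82037452), from 355 ± 104 to 11.1 ± 1.97 CPM, and its neighbour Ccl7 fell by 3.53 on the log2 scale. Plxdc2 (4.54), Hpgd (4.47), which inactivates prostaglandins, and Csf3r (3.59), the G-CSF receptor, also rose. Of 11244 genes tested, 2522 were higher and 2461 lower in low medium (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). A fit of the compared groups alone turned the larger side, with 49.3% higher in place of 50.6%. With libraries summed in pairs the count was 2969, and omission of any library left 4376 to 4680.

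Of 38 cell cycle genes 34 fell and 4 did not pass (34 lower adjusted over the list alone, camera adjusted p = 6.7e-18). Mcm5 of the replicative helicase fell by 2.60 ± 0.22 and Pcna, the replication clamp, fell by 1.75 ± 0.14 on the log2 scale. Glycolysis genes fell in 15 of 20 (16 adjusted over the list alone, camera adjusted p = 3.53e-10). Lactate dehydrogenase Ldha went from 696 ± 205 to 138 ± 8.48 CPM, the kinase Pgk1 from 850 ± 129 to 165 ± 23.9 CPM and the lactate exporter Slc16a3 from 77.7 ± 9.49 to 16.1 ± 1.55 CPM. ATF4 and amino acid targets fell in 16 and rose in 3 of 23 (the same counts adjusted over the list alone, camera adjusted p = 1.52e-06). Among them, the serine synthesis enzyme Phgdh fell by 3.75 and Psat1 fell by 2.88. Fatty acid synthesis fell in 13 of 14 (13 adjusted over the list alone, camera adjusted p = 5.39e-06). The desaturase Scd2 fell by 3.12 and fatty acid synthase, Fasn, fell by 2.10. Cholesterol synthesis fell in 18 of 24 (19 adjusted over the list alone, camera adjusted p = 6.59e-06), and squalene epoxidase, Sqle, fell by 1.71. Pentose phosphate and nucleotide synthesis fell in 22 of 29 (24 adjusted over the list alone, camera adjusted p = 8.69e-10). Ribosome biogenesis fell in 16 and rose in 1 of 24 (the same counts adjusted over the list alone, camera adjusted p = 2.14e-06). Of the polyamine enzymes, Srm fell by 2.93 and Odc1 fell by 2.30. Autophagy genes rose in 19 and fell in 1 of 30 (22 and 1 adjusted over the list alone, camera adjusted p = 7.09e-05). Wipi2 and Gabarapl1, both of the forming autophagosome, rose by 1.62 and 1.15. LXR targets rose in 6 of 10 (6 adjusted over the list alone, camera adjusted p = 2.47e-05). The lipid carrier Apoe (Entrez 11816, chromosome 7 at 19696244 to 19701310) went from 447 ± 53.3 to 3750 ± 615 CPM and the cholesterol exporter Abca1 rose by 2.59. These 9 lists also passed with an estimated correlation.

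Other lists passed only with the preset correlation. Oxidative phosphorylation genes fell in 44 and rose in 2 of 70 (45 and 2 adjusted over the list alone, camera adjusted p = 1.05e-08). Cytochrome c, Cycs, fell by 2.10, and the list had adjusted p = 0.185 with an estimated correlation. TCA cycle genes fell in 11 of 21 (11 adjusted over the list alone, camera adjusted p = 0.00105), with adjusted p = 0.116 with an estimated correlation. Macrophage identity genes rose in 15 and fell in 3 of 25 (the same counts adjusted over the list alone, camera adjusted p = 0.00103). Cx3cr1, the fractalkine receptor, went from 217 ± 29.3 to 1140 ± 115 CPM, and the list had adjusted p = 0.0767 with an estimated correlation. Lysosome genes rose in 18 and fell in 5 of 42 (19 and 5 adjusted over the list alone, camera adjusted p = 0.024), with adjusted p = 0.512 with an estimated correlation. Cytosolic ribosomal proteins fell in 14 and rose in 2 of 56 (13 and 2 adjusted over the list alone, camera adjusted p = 0.0193), with adjusted p = 0.609 with an estimated correlation. MHC class II genes rose in 5 of 7 (5 adjusted over the list alone, camera adjusted p = 0.0357), with adjusted p = 0.295 with an estimated correlation. Hypoxia targets, 5 higher and 9 lower of 20 (the same counts adjusted over the list alone), did not pass as a list (camera adjusted p = 0.0785).

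In knockout cells in low medium all 38 cell cycle genes fell, and cholesterol and fatty acid synthesis fell too. The cell cycle median was −3.15 (38 lower adjusted over the list alone, camera adjusted p = 1.99e-33, and adjusted p = 0.00012 with an estimated correlation). Rrm2, which makes deoxynucleotides, went from 85.1 ± 15.3 to 2.12 ± 0.875 CPM and Uhrf1, which maintains DNA methylation, from 55.7 ± 8.31 to 1.49 ± 0.327 CPM. Thbs1 rose by 5.93 ± 0.26 and Samd4, an RNA-binding regulator, by 6.90 ± 0.49 on the log2 scale. Cholesterol synthesis fell in 22 of 24 (23 adjusted over the list alone, camera adjusted p = 1.42e-10). Fatty acid synthesis fell in 12 of 14 (12 adjusted over the list alone, camera adjusted p = 6.22e-08). Both also passed with an estimated correlation. Glycolysis fell in 16 and rose in 2 of 20 (the same counts adjusted over the list alone, camera adjusted p = 2.7e-09). Nucleotide synthesis fell in 22 of 29 (22 adjusted over the list alone, camera adjusted p = 2.73e-10). ATF4 targets fell in 15 and rose in 3 of 23 (the same counts adjusted over the list alone, camera adjusted p = 2.49e-06). Ribosome biogenesis fell in 16 of 24 (16 adjusted over the list alone, camera adjusted p = 3.46e-06). Autophagy genes rose in 18 and fell in 1 of 30 (the same counts adjusted over the list alone, camera adjusted p = 0.000316). LXR targets rose in 6 and fell in 1 of 10 (the same counts adjusted over the list alone, camera adjusted p = 0.000364). These 6 lists also passed with an estimated correlation, at adjusted p = 0.00012 to 0.0321. Interferon genes rose in 23 and fell in 1 of 36 (24 and 1 adjusted over the list alone, camera adjusted p = 0.0159), with adjusted p = 0.502 with an estimated correlation. Beside these groups, neutrophil markers rose in 8 of 11 (9 adjusted over the list alone, camera adjusted p = 0.000738, and adjusted p = 0.0223 with an estimated correlation). In all, 2986 genes were higher and 2436 lower in low medium (edgeR), around a median log2 change over all genes of 0.10. A fit of the compared groups alone turned the larger side, with 48.6% higher in place of 55.1% and a median of 0.01. The count was 3539 with libraries summed in pairs, and omission of any library left 4855 to 5261.

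LPS raised every measured member of the inflammatory and interferon lists in wild-type cells in normal medium. All 39 inflammatory genes rose (39 adjusted over the list alone, median 6.20, camera adjusted p = 1.49e-48) and all 36 interferon genes rose (36 adjusted over the list alone, median 3.88, camera adjusted p = 6.76e-38). Tnf, the cytokine (Entrez 21926, chromosome 17 at 35199367 to 35202007), went from 30.3 ± 5.21 to 2760 ± 191 CPM, and Ccl5, a chemokine for T cells, from 6.63 ± 1.81 to 1740 ± 133 CPM. Il12b, a subunit of interleukin 12, rose by 8.87 ± 0.40 and Ptgs2, the inducible prostaglandin synthase, by 8.43 ± 0.36 on the log2 scale. Among interferon genes the antiviral Rsad2 rose by 6.24 ± 0.26 and Mx1 by 5.78 ± 0.27. Csf1, the gene of M-CSF itself, rose from 5.59 ± 0.591 to 214 ± 23.1 CPM, and the survival gene Birc3 by 3.04 on the log2 scale. Gcnt1, a glycan-branching enzyme, fell by 4.28 ± 0.25 on the log2 scale. E2f2, a cell cycle transcription factor, fell by 3.85 ± 0.34 and Gpr183, an oxysterol receptor, fell by 3.34 ± 0.22. In all, 2053 genes rose and 2008 fell (edgeR), and the larger side turned in most other settings (44.5% higher with RLE size factors and with DESeq2, in place of 50.6%). With libraries summed in pairs 2594 passed, and omission of any library left 3596 to 3944.

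Both inflammatory lists also passed with an estimated correlation (adjusted p = 4.03e-07 and 0.00041), and the other lists that LPS moved in these cells did not. Cell cycle genes fell in 18 of 38 (19 adjusted over the list alone, camera adjusted p = 4.13e-05). Cdc6, which loads the helicase, fell by 3.06, and the list had adjusted p = 0.199 with an estimated correlation. Fatty acid synthesis fell in 4 of 14 (4 adjusted over the list alone, camera adjusted p = 0.0234). Scd2 fell by 2.19, and the list had adjusted p = 0.103 with an estimated correlation. MHC class II rose in 4 of 7 (4 adjusted over the list alone, camera adjusted p = 0.00631, H2-Ab1 by 2.14), with adjusted p = 0.199 with an estimated correlation. Apoptosis and survival genes rose in 12 and fell in 4 of 25 (13 and 4 adjusted over the list alone, camera adjusted p = 0.00223), with adjusted p = 0.0684 with an estimated correlation. Oxidative phosphorylation rose in 11 of 70 (3 adjusted over the list alone, camera adjusted p = 0.0113, Cycs by 0.80). Ribosomal proteins rose in 9 of 56 (0 adjusted over the list alone, camera adjusted p = 0.0113). Both had adjusted p = 0.624 with an estimated correlation. Damage- and lipid-associated genes rose in 7 and fell in 1 of 24 (the same counts adjusted over the list alone, camera adjusted p = 0.0234), with adjusted p = 0.563 with an estimated correlation. Neutrophil markers rose in 5 of 11 (6 adjusted over the list alone, camera adjusted p = 0.0394), with adjusted p = 0.199 with an estimated correlation.

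The inflammatory lists rose in the other 3 settings too. In wild-type cells in low medium 38 of 39 inflammatory and 36 of 36 interferon genes rose (38 and 36 adjusted over the list alone, camera adjusted p = 2.65e-34 and 1.01e-31). In knockout cells the counts were 39 and 36 in normal medium and 38 and 36 in low medium (the same counts adjusted over the list alone, camera adjusted p = 2.32e-44, 1.34e-38, 1.72e-32 and 7.6e-31). All 6 of these tests also passed with an estimated correlation. Of the other lists, ATF4 targets in wild-type cells in low medium passed by both forms, with 13 higher and 3 lower of 23 (the same counts adjusted over the list alone, camera adjusted p = 0.00268, and adjusted p = 0.0101 with an estimated correlation). In low medium Acod1, which makes itaconate, went from 34.7 ± 3.43 to 26700 ± 9600 CPM in wild-type cells, and Sox4, a transcription factor, from 222 ± 15.1 to 1.44 ± 1.06 CPM. In knockout cells in low medium Il12b rose by 10.19 and Ifi205 by 10.24, an interferon gene with close relatives, so that its level is uncertain. There Lpin1, of phospholipid synthesis, fell by 6.98 and the sulfate transporter Slc26a11 fell by 6.64. In knockout cells in normal medium the chemokine Cxcl1 went from 0.571 ± 0.168 to 501 ± 86.2 CPM, and Lhfpl2 fell by 4.18. Wild-type cells had 3041 genes higher and 3783 lower in low medium, and knockout cells 2349 higher and 2447 lower in normal and 2979 higher and 4611 lower in low medium (edgeR). The median log2 change over all genes was −0.18 in wild-type and −0.36 in knockout cells in low medium, the latter −0.25 with RLE size factors, and the changes of the named genes exceeded these shifts. In knockout cells in normal medium, 50.7% were higher with libraries summed in pairs and 50.4% in a fit of the compared groups alone, in place of 49.0%.

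By the interaction test, the response of wild-type cells to LPS differed between the media for 2649 genes. The interaction contains the change between media without LPS with its sign turned, so lists that low medium had lowered tend to a positive value through the shared controls. It was positive for 1206 and negative for 1443 genes (edgeR), around a median of −0.14 over all genes. Interferon genes responded more in low medium in 24 of 36 (27 adjusted over the list alone, camera adjusted p = 4.06e-15). Inflammatory genes responded more in 15 and less in 3 of 39 (16 and 3 adjusted over the list alone, camera adjusted p = 5.87e-06). Glycolysis responded more in 10 of 20 (11 adjusted over the list alone, camera adjusted p = 3.64e-08) and ribosome biogenesis more in 14 and less in 1 of 24 (16 and 2 adjusted over the list alone, camera adjusted p = 1.28e-05). Cholesterol synthesis responded more in 12 and less in 2 of 24 (the same counts adjusted over the list alone, camera adjusted p = 7.73e-05). ATF4 targets responded more in 9 and less in 2 of 23 (10 and 2 adjusted over the list alone, camera adjusted p = 3.33e-05). Hypoxia targets responded more in 6 and less in 3 of 20 (the same counts adjusted over the list alone, camera adjusted p = 0.00718) and autophagy genes more in 3 and less in 12 of 30 (4 and 15 adjusted over the list alone, camera adjusted p = 0.011). These 8 lists also passed with an estimated correlation, at adjusted p = 0.00174 to 0.0302. Cell cycle genes had 3 positive and 15 negative interactions of 38 (3 and 19 adjusted over the list alone, camera adjusted p = 0.000241). LXR targets had 5 negative of 10 (5 adjusted over the list alone, camera adjusted p = 0.0223). Both had adjusted p = 0.199 with an estimated correlation. Lysosome genes had 6 negative and 1 positive of 42 (the same counts adjusted over the list alone, camera adjusted p = 0.0223), with adjusted p = 0.567 with an estimated correlation. The interaction was 4.69 ± 0.37 for Tnfsf9, a T cell costimulator, 3.94 ± 0.24 for the cyclin gene Ccnd2, 3.40 ± 0.26 for the stress gene Nupr1 and −3.79 ± 0.33 for Thbs1. RLE size factors gave 52.8% and DESeq2 52.1% positive in place of 45.5%. Summed in pairs, the libraries gave 853 genes, and omission of any library left 2315 to 2592.

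In normal medium without LPS the genotypes differed in few genes, and the central metabolic lists differed little. This comparison asked what loss of Trem2 changes when M-CSF is plentiful. Among the named genes besides Trem2, low levels in knockout cells were found for Erdr1 (Entrez 170942, chromosome X at 170010526 to 170018797), at 3.17 ± 1.68 against 352 ± 113 CPM, and for Aacs. Aacs, which uses ketone bodies for lipid synthesis (Entrez 78894, chromosome 5 at 125475873 to 125517405), stood at 3.73 ± 2.43 against 38.5 ± 2.19 CPM. Erdr1 lies in repeated sequence at the pseudoautosomal boundary, so its level is uncertain. Npy, a neuropeptide, was lower by a log2 change of −1.93 ± 0.23, the motor Myo1e by −1.91 ± 0.20 and the protocadherin Pcdh7 by −1.81 ± 0.25. Wdfy1, an endosomal adaptor, was higher by 2.43 ± 0.22, the iron exporter Slc40a1 by 1.66 ± 0.18 and the cholesterol exporter Abcg1 by 1.29 ± 0.21. Erdr1, Aacs, Wdfy1, Slc40a1 and Abcg1 passed in the same direction in all 4 conditions. For them a strain difference cannot be told apart from an effect of Trem2 loss. In all, 84 genes were higher and 125 lower in knockout cells (edgeR). DESeq2 called 344 and voom 552, against 39 with libraries summed in pairs, and omission of any library left 144 to 188.

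ATF4 targets were the list that differed by both forms of the test, with 1 of 23 higher (1 adjusted over the list alone, median 0.27, camera adjusted p = 0.000344, and adjusted p = 0.00203 with an estimated correlation). The member that passed was Atf5, a transcription factor of the stress response, at 30.3 ± 1.81 against 17.3 ± 3.23 CPM (edgeR adjusted p = 0.0099), which missed the threshold without wild-type library 1 (edgeR adjusted p = 0.059). Damage- and lipid-associated genes, a list that includes Trem2, were lower in 5 and higher in 1 of 24 (7 and 3 adjusted over the list alone, camera adjusted p = 0.0229). That list had adjusted p = 0.495 with an estimated correlation and 0.17 by ranks. Lpl, lipoprotein lipase, stood at 1780 ± 68.2 against 3650 ± 309 CPM and Axl, a receptor for apoptotic cells, at 7.55 ± 1.69 against 17.1 ± 1.05 CPM. With libraries summed in pairs, Lpl, Axl and Atf5 missed the threshold (edgeR adjusted p = 0.17, 0.062 and 0.37). Interferon genes had a median of −0.29 with 0 of 36 passing by edgeR (0 adjusted over the list alone, camera adjusted p = 0.014), with adjusted p = 0.495 with an estimated correlation. Oxidative phosphorylation (median 0.08) and ribosome biogenesis (median −0.25) had no member past the threshold by edgeR (0 and 1 adjusted over the list alone, camera adjusted p = 0.0412 each), with adjusted p = 0.818 and 0.464 with an estimated correlation. Cell cycle genes had 0 of 38 past the threshold (0 adjusted over the list alone, median −0.12, camera adjusted p = 0.381). Glycolysis had 1 lower of 20 (1 adjusted over the list alone, camera adjusted p = 0.636) and cholesterol synthesis 0 of 24 (0 adjusted over the list alone, camera adjusted p = 0.141).

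In low M-CSF without LPS the knockout cells had far lower expression of cell division genes than wild-type cells, with lower cholesterol synthesis and more Apoe. This comparison asked what loss of Trem2 changes when the growth factor is scarce. Of 38 cell cycle genes 35 were lower and 3 did not pass (36 adjusted over the list alone, median −1.87, camera adjusted p = 3.08e-39, and adjusted p = 3.68e-05 with an estimated correlation). The cyclin Ccna2 (Entrez 12428, chromosome 3 at 36564865 to 36573038) stood at 6.39 ± 2.14 in knockout against 32.2 ± 8.54 CPM in wild-type cells. Pclaf, which binds the replication clamp (Entrez 68026, chromosome 9 at 65890323 to 65903551), stood at 15.9 ± 5.59 against 159 ± 75.9 CPM (edgeR adjusted p = 3.2e-11). Claspin, Clspn, which guards the replication fork, was lower by a log2 change of −3.40 ± 0.34, the cytokinesis motor Kif23 by −2.65 ± 0.28 and the mitotic ubiquitin enzyme Ube2c by −2.33 ± 0.24. Cholesterol synthesis genes were lower in 10 of 24 (16 adjusted over the list alone, median −0.65, camera adjusted p = 1.09e-08, and adjusted p = 0.00117 with an estimated correlation). The sterol carrier Stard4 stood at 28.9 ± 2.42 against 68.4 ± 4.63 CPM.

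Beside the fall in cell cycle genes, neutrophil markers were higher in knockout cells in low medium. They were higher in 7 of 11, with 0 lower (9 higher and 1 lower adjusted over the list alone, median 1.45, camera adjusted p = 3.99e-05, and adjusted p = 0.00795 with an estimated correlation). Their members S100a8 (65.7 against 26.9 CPM) and S100a9 (86.0 against 40.9 CPM), antimicrobial proteins, were chosen after their values were seen. Apoe, which passed within the LXR list, stood at 10400 ± 682 against 3750 ± 615 CPM (edgeR adjusted p = 5.7e-10), and Abcg1 at 114 ± 9.69 against 56.0 ± 10.4 CPM. LXR targets were higher in 4 and lower in 1 of 10 (5 and 1 adjusted over the list alone, camera adjusted p = 0.0366), with adjusted p = 0.228 with an estimated correlation. Lysosome genes were higher in 11 and lower in 3 of 42 (18 and 6 adjusted over the list alone, camera adjusted p = 0.0163), the protease Ctsd by 0.90 ± 0.16, with adjusted p = 0.521 with an estimated correlation. Interferon genes were higher in 10 of 36 (14 adjusted over the list alone, camera adjusted p = 0.0227), Rsad2 by 0.91 ± 0.21, with adjusted p = 0.588 with an estimated correlation. Pentose phosphate and nucleotide synthesis genes were lower in 8 and higher in 1 of 29 (the same counts adjusted over the list alone, camera adjusted p = 0.0281). The folate enzyme Mthfd2 differed by −1.62 ± 0.20, and the list had adjusted p = 0.159 with an estimated correlation. Fatty acid synthesis was lower in 3 of 14 (3 adjusted over the list alone, camera adjusted p = 0.0419), the desaturase Fads2 standing at 5.77 ± 1.72 against 23.5 ± 6.79 CPM. Alternative activation was higher in 5 and lower in 1 of 13 (the same counts adjusted over the list alone, camera adjusted p = 0.0325), the lectin Clec10a by 1.81 ± 0.33. Both had adjusted p = 0.12 with an estimated correlation. By ranks the LXR (adjusted p = 0.127), nucleotide synthesis (0.0923), fatty acid synthesis and alternative activation lists (0.0699 each) missed the threshold too. Glycolysis (camera adjusted p = 0.285), the TCA cycle (0.58), oxidative phosphorylation (0.583) and damage- and lipid-associated genes (0.232) did not pass.

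Outside the lists, knockout cells in low medium had more Gpx3 (2.26 ± 0.27), a glutathione peroxidase, Wdfy1 (2.15 ± 0.22), Gdf15 (2.11 ± 0.26), a stress cytokine, and Nnt (1.75 ± 0.21), a mitochondrial transhydrogenase, on the log2 scale. They had less Erdr1 (2.51 ± 0.894 against 149 ± 32 CPM) and Pcdh7 (16 ± 2.40 against 228 ± 34.9 CPM). Wdfy1, Nnt and Erdr1 passed in the same direction in all 4 conditions. For them a strain difference cannot be told apart from an effect of Trem2 loss. Scgb1a1, a secreted protein of airway epithelium, stood at 59.3 ± 41.9 CPM in wild-type and 0.344 ± 0.353 CPM in knockout cells, the latter near the limit of 3 counts. Sftpc, a surfactant gene of lung chosen after its values were seen, moved with it in these libraries, at 9.07 ± 8.44 raw CPM in wild-type and 0 in knockout cells. In all, 870 genes were higher and 1009 lower in knockout cells (edgeR), and 2440 genes had no overlap between the 8 libraries, where chance gives 2 of 70 arrangements. With libraries summed in pairs the count was 621, of which 25.1% were higher against 46.3% here (51.7% with voom), and Rsad2 then missed the threshold (edgeR adjusted p = 0.098). Omission of any library left 1260 to 1781.

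**Figure D2:**
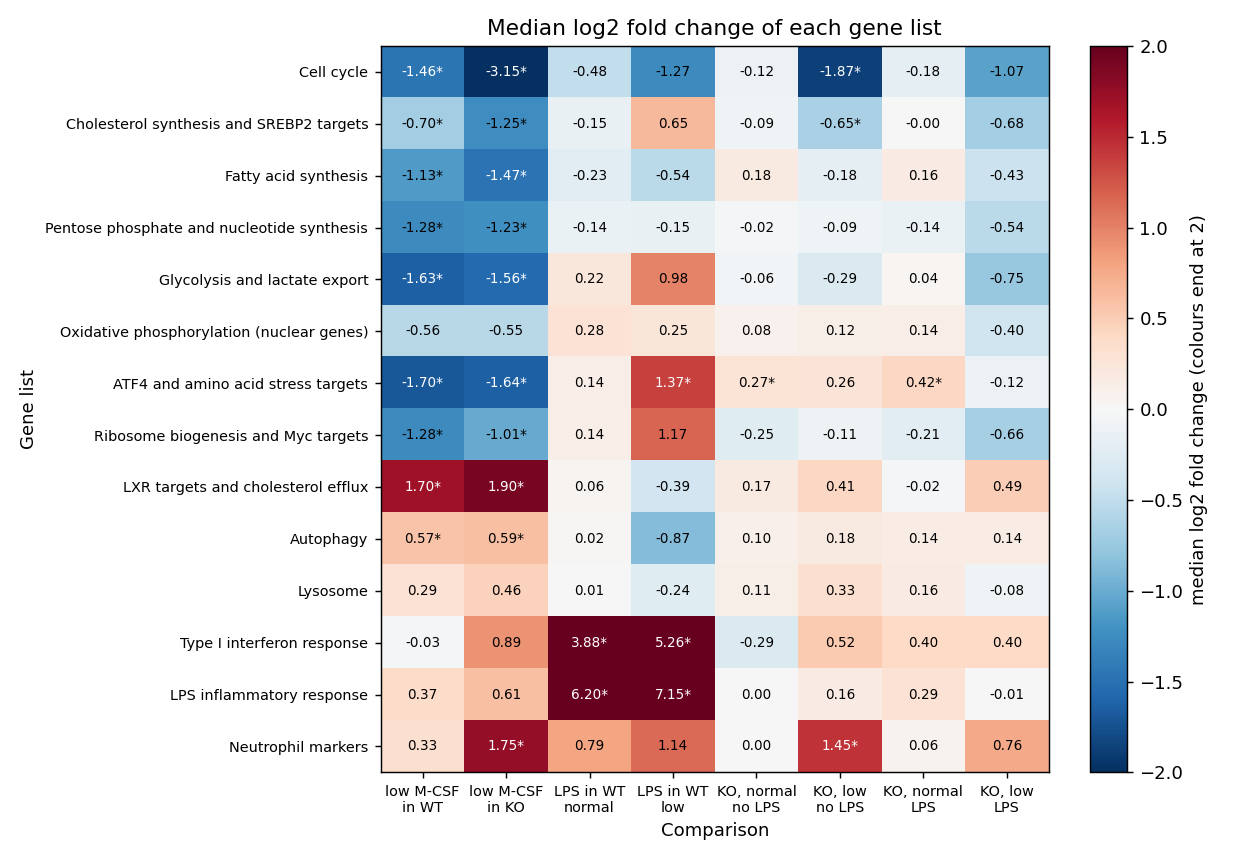
Median log2 fold change (colour, blue lower and red higher, colours end at −2 and 2) of 14 gene lists in 8 comparisons; an asterisk marks a camera adjusted p under 0.05 with an estimated correlation. In low medium without LPS the knockout median of the cell cycle list was −1.87 and that of cholesterol synthesis −0.65.

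By the interaction test, the genotype difference without LPS varied with the medium for 519 genes, and the cell cycle list had the smallest camera p. The interaction was negative for 361 and positive for 158 genes (edgeR). Cell cycle genes had 31 negative interactions of 38 (35 adjusted over the list alone, median −1.73, camera adjusted p = 5.11e-47, and adjusted p = 8.32e-06 with an estimated correlation). It was −3.54 ± 0.37 for Pclaf, −3.23 ± 0.33 for Uhrf1 and −3.06 ± 0.33 for Spc25, of the kinetochore. Cholesterol synthesis had 3 negative of 24 (5 adjusted over the list alone, camera adjusted p = 2.67e-06, and adjusted p = 0.00756 with an estimated correlation). Fatty acid synthesis had 2 of 14 (3 adjusted over the list alone, camera adjusted p = 0.00442, and adjusted p = 0.0209 with an estimated correlation). Neutrophil markers had 4 positive interactions of 11 (5 adjusted over the list alone, camera adjusted p = 0.000178, and adjusted p = 0.0183 with an estimated correlation). Apoe (1.29 ± 0.20), the mitochondrial iron importer Slc25a37 (1.95 ± 0.31) and the interferon gene Ifit3 (1.93 ± 0.37) had positive interactions. Interferon genes had 4 positive of 36 (13 adjusted over the list alone, camera adjusted p = 1.46e-05), with adjusted p = 0.324 with an estimated correlation. Nucleotide synthesis had 5 negative of 29 (7 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0167), with adjusted p = 0.156 with an estimated correlation and 0.169 by ranks. Summed in pairs, the libraries gave 97 genes, 5.15% of them positive against 30.4% here, and Apoe missed the threshold (edgeR adjusted p = 0.092). Voom called 1128, 45.5% of them positive, a fit of the 4 groups alone gave 20.2% positive, and omission of any library left 398 to 509.

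**Figure D3:**
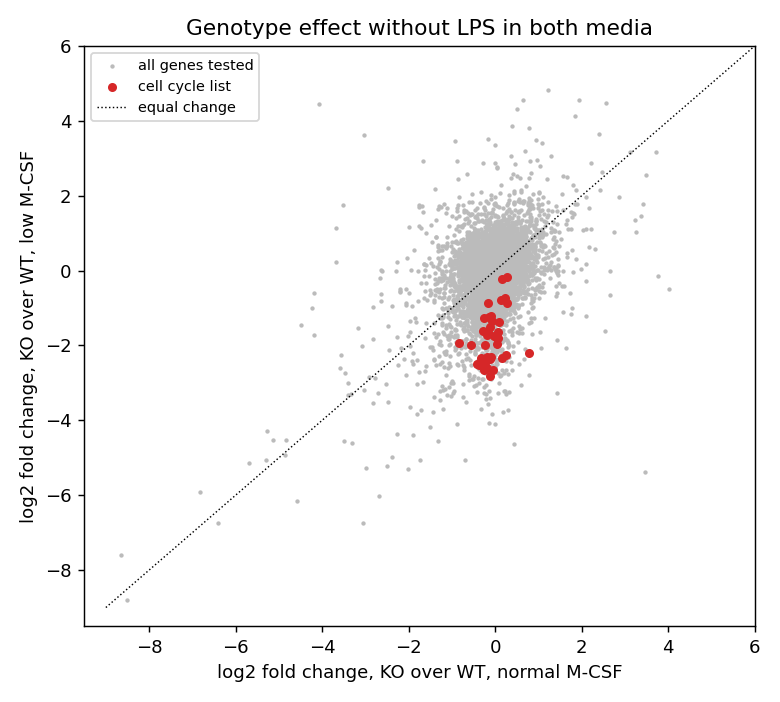
Log2 fold change of knockout over wild-type without LPS in normal medium (horizontal axis) and in low medium (vertical axis) for 11244 genes; points are genes, cell cycle genes are coloured, and the diagonal marks equal change. All 38 cell cycle genes lay below the diagonal.

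With LPS in low medium, the genotypes differed in 2147 genes, 922 higher and 1225 lower in knockout cells (edgeR), and many metabolic genes were lower. Glycolysis genes were lower in 12 and higher in 1 of 20 (14 and 1 adjusted over the list alone, camera adjusted p = 4.29e-09). Cholesterol synthesis was lower in 10 of 24 (12 adjusted over the list alone, camera adjusted p = 0.00011) and cell cycle genes were lower in 19 and higher in 2 of 38 (22 and 2 adjusted over the list alone, camera adjusted p = 2.45e-08). Nucleotide synthesis was lower in 8 of 29 (11 adjusted over the list alone, camera adjusted p = 0.00147) and ribosome biogenesis lower in 10 of 24 (14 adjusted over the list alone, camera adjusted p = 2.2e-05). All 5 lists had adjusted p = 0.0535 with an estimated correlation. Oxidative phosphorylation was lower in 26 of 70 (31 lower and 1 higher adjusted over the list alone, camera adjusted p = 2.82e-09) and ribosomal proteins in 16 of 56 (26 lower and 1 higher adjusted over the list alone, camera adjusted p = 2.82e-09). Interferon genes were higher in 10 of 36 (10 adjusted over the list alone, camera adjusted p = 9.86e-08). These 3 lists had adjusted p = 0.143 with an estimated correlation. TCA cycle genes were lower in 4 of 21 (4 adjusted over the list alone, camera adjusted p = 0.0147, and adjusted p = 0.189 with an estimated correlation). Damage- and lipid-associated genes were lower in 10 and higher in 5 of 24 (the same counts adjusted over the list alone, camera adjusted p = 0.0147, and adjusted p = 0.304 with an estimated correlation and 0.135 by ranks). LXR targets (4 higher and 1 lower of 10, or 4 and 2 adjusted over the list alone), macrophage identity (6 and 1 of 25 by both counts) and apoptosis genes (5 higher of 25, or 5 and 1 lower adjusted over the list alone) passed as higher, each with adjusted p = 0.143 with an estimated correlation. By ranks LXR targets had adjusted p = 0.251. Neutrophil markers were higher in 2 of 11 (3 adjusted over the list alone, camera adjusted p = 0.00483), with adjusted p = 0.0675 with an estimated correlation.

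Besides Trem2 and Erdr1, the largest named differences in low medium with LPS were in Abcg1, higher at 117 ± 34.8 against 18.6 ± 4.19 CPM, and Sdc1, a proteoglycan, lower at 6.27 ± 1.77 against 54.3 ± 16.3 CPM. The nucleotide hydrolase Enpp4 (Entrez 224794, chromosome 17 at 44096307 to 44105809) was higher at 230 ± 68.8 against 58.2 ± 12.0 CPM. H2-T23 was higher at 34.7 ± 23 against 8.28 ± 2.85 CPM. Abcg1, Enpp4 and H2-T23, the largest rises by the naming rule here, all lie on chromosome 17, as Trem2 does. Erdr1 stood at 4.84 ± 3.19 against 352 ± 66.1 CPM. With RLE size factors 53.2% of the genes called were higher in place of 42.9%. DESeq2 (52.1%), voom (52%) and a fit of the compared groups alone (55.3%) turned the larger side too. It stayed the lower side without the low-count filter (44.1% higher), with the block (42.8%) and with thinned libraries (41.8%). Voom called 1399, the fit of the compared groups alone 1037, and 485 passed with libraries summed in pairs (32.4% higher). Omission of any library left 1547 to 2190.

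With LPS in normal medium, 223 genes were higher and 231 lower in knockout cells (edgeR), and ATF4 targets again stood out. They were higher in 2 of 23 (4 adjusted over the list alone, median 0.42, camera adjusted p = 4.73e-06, and adjusted p = 0.000342 with an estimated correlation). Interferon genes were higher in 6 of 36 (12 adjusted over the list alone, camera adjusted p = 3.95e-11). Inflammatory genes were higher in 5 of 39 (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 4.73e-06). Both had adjusted p = 0.0544 with an estimated correlation. Ribosome biogenesis was lower in 2 of 24 (6 adjusted over the list alone, camera adjusted p = 9.18e-05) and osteoclast markers in 2 of 7 (2 adjusted over the list alone, camera adjusted p = 0.00753), also with adjusted p = 0.0544 with an estimated correlation. Autophagy genes were higher in 2 of 30 (2 adjusted over the list alone, camera adjusted p = 0.0333, and adjusted p = 0.0544 with an estimated correlation). Oxidative phosphorylation, lysosome, ribosomal protein, cell cycle and apoptosis lists passed with at most 2 members called each way, and lost the call at adjusted p = 0.229 to 0.561 with an estimated correlation. The chemokine Cxcl9, induced by interferon, stood at 122 ± 14.3 against 33.6 ± 6.73 CPM (edgeR adjusted p = 2.3e-06). Enpp4 stood at 173 ± 5.98 against 41.5 ± 4.10 CPM and Wdfy1 at 77.5 ± 7.74 against 14.3 ± 1.88 CPM, while Erdr1 stood at 2.90 ± 1.78 against 321 ± 33.2 CPM. The count was 682 by DESeq2, 921 by voom, 866 in a fit of the compared groups alone and 43 with libraries summed in pairs (37.2% higher against 49.1% here). RLE size factors and DESeq2 had 50.9% higher, a fit of the compared groups alone 52.8%, thinned libraries 52.1% and voom 54.3%. It was 222 without wild-type library 2, 289 without wild-type library 4, and 287 and 302 without knockout library 3 or 4, with 361 the highest of the omissions.

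The interaction test of genotype with LPS passed for more genes in low than in normal medium, a difference in counts that was not itself tested. In low medium it passed for 1800 genes, 845 positive and 955 negative (edgeR), around a median of −0.13 over all genes. The interaction contains the genotype difference without LPS with its sign turned, so its sign alone does not give the direction of the difference with LPS, here or in normal medium. It was positive for the transcription factors Klf4 (2.82 ± 0.28) and Fos (3.24 ± 0.36) and for Tnip3 (2.33 ± 0.20), an inhibitor of NF-kB. It was negative for Trem2 (−3.76 ± 0.30), Iscu (−1.52 ± 0.22), a scaffold for iron-sulfur clusters, and Usf2 (−1.92 ± 0.24), a transcription factor. Oxidative phosphorylation had 18 negative and 3 positive of 70 (32 and 4 adjusted over the list alone, camera adjusted p = 1.37e-06). Glycolysis had 6 negative of 20 (8 adjusted over the list alone, camera adjusted p = 0.000566), and the cell cycle 9 positive of 38 (12 positive and 1 negative adjusted over the list alone, camera adjusted p = 0.00195), although that list was lower in knockout cells with LPS as well. The TCA cycle, ribosome biogenesis and ribosomal protein lists passed with negative medians. All 6 lists had adjusted p = 0.37 with an estimated correlation, and ribosome biogenesis had adjusted p = 0.11 by ranks. RLE size factors gave 60.8%, DESeq2 58.8% and voom 55.7% positive in place of 46.9%. A fit of the 4 groups alone gave 61.5% and summed libraries 58.2%. The negative side stayed larger with the block (47.1% positive), without the low-count filter (49.3%) and with thinned libraries (49.6%). Voom called 1085, the fit of the 4 groups alone 959, and 91 passed with libraries summed in pairs. Omission of any library left 1225 to 2006.

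In normal medium the genotype by LPS interaction passed for 60 genes, 37 positive and 23 negative (edgeR), with 1179 at an unadjusted p under 0.05. Klf4 (1.70 ± 0.28) was positive, and Csf1 (−1.50 ± 0.23) and Trem2 (−2.15 ± 0.29) were negative. Csf1 stood at 19 ± 0.87 CPM in knockout against 5.59 ± 0.591 CPM in wild-type cells without LPS and at 259 ± 24.8 against 214 ± 23.1 CPM with it. Interferon genes had 4 positive of 36 (13 adjusted over the list alone, median 0.78, camera adjusted p = 2.41e-13), with adjusted p = 0.0521 with an estimated correlation. Inflammatory genes had 0 of 39 past the threshold by edgeR (2 positive and 1 negative adjusted over the list alone, camera adjusted p = 0.0262), with adjusted p = 0.732 with an estimated correlation. The Trem family list had 1 negative of 6 (2 adjusted over the list alone, camera adjusted p = 0.0185), with adjusted p = 0.0521 with an estimated correlation and 0.216 by ranks. With libraries summed in pairs edgeR called 0 genes, with 520 at an unadjusted p under 0.05, against 211 by DESeq2 and 177 by voom on the separate libraries. A fit of the 4 groups alone called 120 and no low-count filter 102. The count was 30 and 36 without knockout library 2 or 3 without LPS, 31 without knockout library 4 with LPS, 36, 34 and 31 without wild-type library 1, 2 or 4 with LPS, and 39 without wild-type library 3 without LPS.

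Markers of other cell types gave few further differences between genotypes. Osteoclast markers were lower in knockout cells in low medium without LPS in 1 of 7 (2 adjusted over the list alone, camera adjusted p = 0.0215), with adjusted p = 0.12 with an estimated correlation. In the same comparison monocyte markers split, 2 higher and 3 lower of 8 (the same counts adjusted over the list alone), with a median of 0.38, a mean of 0.03 and a test on the lower side (camera adjusted p = 0.58). Dendritic cell markers had 0 of 4 past the threshold (0 adjusted over the list alone, camera adjusted p = 0.723). Stromal markers had 0 of 3 (0 adjusted over the list alone, median 0.47, test on the lower side, camera adjusted p = 0.96). Hypoxia targets had 2 higher and 2 lower of 20 (the same counts adjusted over the list alone), a median of −0.11 and a mean of 0.06 (camera adjusted p = 0.809). Lists that passed had a median, mean and test of the same sign in each comparison. The lymphocyte list had 1 gene tested, Cd79b of the B cell receptor, at 2.67 in knockout and 3.79 CPM in wild-type cells in low medium without LPS (edgeR adjusted p = 0.42). The erythroid list had Car2 and Epor, at 0.0681 against 0.191 CPM and 1.77 against 0.544 CPM there (edgeR adjusted p = 0.49 and 0.2). Of the sex-linked list only Xist passed the filter, at 782 against 806 CPM there (edgeR adjusted p = 0.89). None of the 9 mast cell markers passed the filter, and none of the 15 mitochondrially encoded transcripts was among the identifiers, so respiration genes here are nuclear genes alone. Cd79b, Car2, Epor and Xist stand outside the naming rule and were chosen after their values were seen, as the tested members of lists too small to test.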

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

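Chosen only after the results were seen were the tests for a lower share of macrophages and for donor DNA on chromosome 17 beyond the window around Trem2, and both settings that thin or sum libraries. Sftpc, Sftpa1 and Ager stand outside the naming rule and were also chosen after their values were seen. So do S100a8 and S100a9 as genes named in the text, although the prediction that uses them was written before its test was run.

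The first pattern is the number of genotype differences without LPS, 1879 in low and 209 in normal medium. Unequal depth does not account for it: with every library thinned to the smallest total, the low medium still had 9.05 times as many calls. With libraries 1 and 3, and 2 and 4, summed it had 15.9 times as many (621 against 39). The difference thus remained, but summing lowers both counts by construction, and a ratio of such counts also depends on the number of libraries. That ratio cannot show whether near-duplicate libraries contribute. The 1879 and 209 calls came from 1 fit that shares the estimate of spread of a gene over all groups. A smaller spread in low medium could therefore not by itself add calls there, but it could in the separate fits of 8 libraries given below. The genotype changes themselves varied 1.51 times as much in low medium (95% interval 1.34 to 1.71, SD 0.545 against 0.361 over 1995 genes at 100 CPM or more). The interval came from resampling genes as if independent and leaves out the variation between libraries. That ratio compares sizes of change, does not measure the spread within groups, and does not rule out a smaller spread for those fits. The biological explanation in the design, a dependence on M-CSF, stays open as a hypothesis. With the libraries of a group taken as 4 separate samples, chance can be excluded for the low-medium count (1606 in a fit of the 8 libraries, highest other split 32, 1 of 35 splits as large) and cannot for the normal-medium count (193, highest other split 849, 2 of 35), where the larger split joined libraries 1 and 3 of the knockout with 2 and 4 of the wild-type and so points to a structure of the samples.

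The second pattern is a set of 61 genes with the same genotype direction in all 4 conditions, 24 higher and 37 lower in knockout cells, where independent comparisons would give 0.0106 and 0.0251; Wdfy1, Slc40a1, Nnt, Aacs, Abcg1, Enpp4 and Erdr1 are among them. Donor DNA flanking Trem2 does not account for the whole set, as 3 of 59 with a position lay within 10 Mb of it (5.08%, exact 95% interval 1.06 to 14.1; Fisher's exact p = 0.0268 against 123 of 11224 tested genes). A longer donor stretch may contribute, with 8 of 465 tested genes of chromosome 17 outside that window (odds ratio 3.86, 95% interval 1.57 to 8.30, Fisher's exact p = 0.00216). Strain differences elsewhere cannot be told apart from a genotype effect. Blocks of them stay open, as 13 genes had another within 2 Mb against a median of 8 in 10000 random lists (share at least as high 0.124). That count bears only on blocks and cannot detect isolated strain differences. As background, C57BL/6J mice carry a known deletion in Nnt. For Scgb1a1, Sftpc and Sftpa1, lung RNA in the wild-type libraries is a candidate source: of 9 other lung markers, 8 had at least 10 wild-type counts and over 4 times the knockout raw CPM. The most abundant, Scgb1a1 and Sftpc, had 5529 and 894 wild-type counts against 28 and 0 in the knockout, and Ager, with 179 against 102, was the exception.

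The third pattern is the neutrophil list, higher in knockout cells in low medium without LPS, with a median of 1.45 (SE 0.195) over 11 members. This SE, and that of the difference between lists below, came from resampling list members and leaves out the variation between libraries. A lower share of macrophages would raise the markers of every other cell type alike. The medians of monocyte (0.376), dendritic cell (0.426) and stromal markers (0.468) were above 0. These lists had 8, 4 and 3 members tested, and no list passed as a whole, with the monocyte and stromal tests on the lower side, so they decide little. The osteoclast median was −0.664, and the difference between the neutrophil and osteoclast lists was 2.11 (SE 0.494 over list members), which the prediction counts against a lower share. Osteoclast markers also had a negative median in normal medium without LPS (−0.471, camera adjusted p = 0.0541), where neutrophil markers had a median of 0.001. With LPS the osteoclast medians were −1.04 in low (camera adjusted p = 0.0604) and −0.522 in normal medium (camera adjusted p = 0.00753). Negative osteoclast medians are thus not particular to this pattern, although the list did not pass in each of these comparisons. In low medium without LPS the macrophage identity list was not lower, with 5 higher and 2 lower of 25 (8 and 2 adjusted over the list alone, median 0.125, camera adjusted p = 0.463). A lower share of macrophages stays open. Neutrophils in the knockout cultures could not be excluded, and would bring their most abundant transcripts in proportion. S100a8 was higher by 1.29 (SE 0.215, upper 95% limit 1.71) and S100a9 by 1.07 (SE 0.189, upper limit 1.44), and the smaller limit missed the list median by a difference of −0.00684, which lies within the spread of that median. A change of these genes within the macrophages stays open and was not tested.

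Some values were far from the other libraries of their group, in 15 of 268 groups of 4 tested, where chance gives about 1 in 20. In knockout cells in low medium without LPS, library 1 had 5.62 CPM of Ube2c (others 17.4 to 18.7) and 6.99 CPM of Il12b (2.29 to 2.83). In wild-type cells of that medium, library 1 had 7.66 CPM of Clec10a (3.84 to 4.36), library 4 had 191 CPM of Thbs1 (134 to 138) and library 2 had 66.5 CPM of Gabarapl1 (94.4 to 99.9). In wild-type cells in normal medium without LPS, library 1 had 510 CPM of Ccl2 (279 to 318), 150 CPM of Ccl7 (86.7 to 96.1) and 91.8 CPM of Slc16a3 (71.6 to 74.7). Knockout cells there had 0.455 CPM of Scgb1a1 in library 2 (0 in the others) and 41.5 CPM of Klf4 in library 1 (31.4 to 32.2). With LPS in low medium, knockout library 2 had 1.33 CPM of Slc26a11 (4.61 to 4.86), wild-type library 2 had 64.9 CPM of Fos (51.7 to 53.5) and 71.9 CPM of Usf2 (40.8 to 45.3), and wild-type library 1 had 1302 CPM of Ccnd2 (1177 to 1189) and 11389 genes with counts (11134 to 11168).

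Effects that differed between conditions by an interaction test were the genotype difference between media without LPS (519 genes), the genotype difference in the LPS response in low (1800) and normal medium (60), and the medium difference in the LPS response of wild-type cells (2649). Between media the genotype difference changed by −3.54 for Pclaf, −3.23 for Uhrf1, −3.06 for Spc25, 1.29 for Apoe, 1.95 for Slc25a37 and 1.93 for Ifit3. With LPS in low medium it changed by −3.76 for Trem2, 2.82 for Klf4, 2.33 for Tnip3, 3.24 for Fos, −1.52 for Iscu and −1.92 for Usf2, and in normal medium by −2.15 for Trem2, 1.70 for Klf4 and −1.50 for Csf1. The LPS response of wild-type cells differed between media by 3.94 for Ccnd2, 4.69 for Tnfsf9, −3.79 for Thbs1 and 3.40 for Nupr1.

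Other splits of the libraries of a comparison, fitted alone, tested chance with the 4 libraries of a group taken as separate samples. If libraries 1 and 3 and libraries 2 and 4 are duplicates, only the real split and 2 others keep them whole. These are too few for a share under 0.05, and no statement here or above that chance is excluded would hold. As separate samples, chance can be excluded for genotype with LPS in low medium (1037 genes, highest other split 3) and normal medium (866, 63; 43 genes with libraries summed in pairs), for the medium in wild-type (5129, 1) and knockout cells (5392, 235), and for LPS in wild-type cells in normal (4398, 3) and low medium (5881, 0) and in knockout cells in normal (4968, 1) and low medium (6636, 0), with 1 of 35 splits as large in each. Of 100 random splits for the interactions, 5 were as large for genotype by medium, so chance cannot be excluded there (494, highest other 778). No other split drawn kept such pairs whole. For genotype by LPS in low medium 1 of 100 was as large (959, highest other 244), where summed libraries left 91 genes. For medium by LPS in wild-type cells 2 of 100 were as large (2541, highest other 3397). The splits for interactions shuffled genotype, or the medium, within each condition and so also removed its difference there. A low share can therefore not separate the interaction from that difference, and chance is left open for both interactions. In normal medium 3 of 100 were as large for genotype by LPS (120, highest other 908), and with that split and 0 genes from summed libraries chance is left open there. Of the other large splits, 3 of 4 for genotype by medium, 1 of 2 for genotype by LPS in normal medium and the 1 for medium by LPS kept the real division in 1 of the 2 conditions. These carry the difference of that condition into the interaction and do not measure chance alone, so the test for genotype by medium decides little. The split with 908 genes kept neither division and points to a structure of the samples.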

How the results depend on the processing

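Chosen after seeing the data were the thinning of libraries and the summing of libraries 1 with 3 and 2 with 4. No library fell below the depth limit, so omission by depth gave no value. Equal replicate numbers did not pair the samples in the same way throughout. Correlated residuals above 0.1 for every number were found in 1 of 28 pairs of groups, with a mean r of 0.0177 for equal and −0.00584 for other numbers. That mean joins opposite signs. Knockout cells without LPS in low and normal medium had r of −0.288 to −0.217 at every number. Knockout cells without LPS in normal medium and wild-type cells with LPS in low medium had 0.151 to 0.252. A structure shared by groups under different numbers thus stays possible, and a block for the replicate number would not remove it. The block for that number kept all counts within 1.5 times, the lowest ratio being 47 of 60 for genotype by LPS in normal medium. RLE size factors and thinning also kept every count within 1.5 times, and Trem2 kept its direction and its exact p with both other pseudocounts. Of 269 results of named genes, 268 were the same with DESeq2, 267 with RLE size factors and 227 with summed libraries, where 41 missed the threshold. Among list tests 130 of 378 passed, against 46 with an estimated correlation, 131 with the block and 124 by ranks. Summed libraries leave 2 per group, so fewer degrees of freedom lower their counts by construction. The cause of the other changes was not tested.

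With summed libraries the counts were 621 and 39 for genotype in low and normal medium without LPS, 485 and 43 with LPS, 2969 and 3539 for the medium in wild-type and knockout cells, and 2594 for LPS in wild-type cells in normal medium. They were 97 for genotype by medium, 91 and 0 for genotype by LPS in low and normal medium (520 at an unadjusted p under 0.05 by edgeR, and 211 calls by DESeq2 on the separate libraries), and 853 for medium by LPS. DESeq2 gave 344 for genotype in normal medium without LPS, 682 with LPS and 211 for genotype by LPS in normal medium. Voom gave 552 for genotype in normal medium without LPS, 1399 and 921 with LPS in low and normal medium, 1128 for genotype by medium, and 1085 and 177 for genotype by LPS. A fit of the compared groups alone gave 1037 and 866 for genotype with LPS in low and normal medium, and 959 and 120 for genotype by LPS. No low-count filter gave 102 for genotype by LPS in normal medium.

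Omission of each library in turn gave 1260 to 1781 and 144 to 188 for genotype in low and normal medium without LPS, and 1547 to 2190 and 222 to 361 with LPS. For the medium it gave 4376 to 4680 in wild-type and 4855 to 5261 in knockout cells. For LPS it gave 3596 to 3944 and 6527 to 6657 in wild-type cells in normal and low medium, and 4297 to 4633 and 7264 to 7542 in knockout cells. For the interactions it gave 398 to 509 for genotype by medium, 1225 to 2006 and 30 to 60 for genotype by LPS in low and normal medium, and 2315 to 2592 for medium by LPS. Omissions that moved a count by over 1.5 times were, for genotype with LPS in normal medium, knockout library 3 (287) or 4 (302) and wild-type library 2 (222) or 4 (289). For its interaction with LPS they were knockout library 4 with LPS (31), knockout library 2 (30) or 3 (36) without, wild-type library 1 (36), 2 (34) or 4 (31) with, and wild-type library 3 without LPS (39).

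Directions reversed only for Trem family genes that did not pass the test and lay at a few CPM. Trem1 for genotype in low medium without LPS (0.02) became −0.02 with RLE size factors, −0.01 with DESeq2, −0.14 thinned, −0.02 summed and ranged from −0.26 to 1.49 with a library left out. For genotype with LPS in normal medium, Trem3 (−0.43) became 0.06 thinned and Treml4 (0.24) became −0.11 with voom. With a library left out, Treml4 ranged from −0.21 to 0.56 and Treml1 from −3.76 to 0.06 there. Trem3 ranged from −0.79 to 0.05 in low medium without LPS and from −1.23 to 0.02 with LPS, and Trem1 from −0.01 to 0.38 in normal medium without LPS. Many small changes were missed in simulation, which recovered 16.4% of genes changed 1.5-fold in low and 10.4% in normal medium.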
